A study of Drosophila melanogaster with 8 samples.

How the data were processed

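RNA was measured in 8 cultures of Drosophila S2R+ cells, an adherent, haemocyte-like derivative of the Schneider 2 embryonic cell line. Per the labels' protocols, each culture received 30 µg of double-stranded RNA, and total RNA was taken after a further 5 days. The double-stranded RNA was directed against M1BP in 4 cultures and against LacZ, a bacterial gene that serves as the control, in the other 4. The series design calls them biological replicates. Labelling was with Cy3 after a NimbleGen protocol, per the labels, so each array carries 1 sample in 1 colour.

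The deposited table holds log2 expression values, 1 row per FlyBase transcript identifier and 1 column per array. The authors made them with RMA, per the submitters' processing notes, which give no version. RMA (robust multi-array average) is a method that corrects background, normalizes arrays to each other and summarizes each transcript's probes. The log2 scale was read from the values, which run from 4.27 to 15.98. The array design's annotation release, probe sequences, detection calls and raw intensities were not used here, and the genome build is not given in the sources used here. The method brings the arrays to a shared distribution, so a change shared by most transcripts is not visible in these values. It also leaves no depth or background measure per transcript. The number of arrays limits the precision: the median standard error of a log2 difference was 0.16 over the 15473 transcripts. With the replicate number as a block it was 0.12.

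The transcript identifiers were named through the synonyms of a RefSeq gene table of Release 6 with 17872 genes. Of the 15473 identifiers, 44 occurred there. Of these, 17 belonged to 1 gene (9 as a synonym of their own and 8 as part of a longer synonym) and 27 to several genes, which were not named. The remaining 15429 stayed unnamed. Each of the 17 names rests on 1 transcript, and other transcripts of the same gene may be among the unnamed ones. No identifier was tied to M1BP, so its depletion was not analysed here. Of 41 gene lists fixed in advance (such as ribosomal proteins, cell cycle, immune effectors, haemocyte, neuron and muscle markers), none had 5 named members and 2 had 1 each (LanA among haemocyte markers, kis among Polycomb and trithorax genes). The planned list tests and promoter motif tests were therefore not run. No coordinates are given, because the build of the array design is not named.

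The groups, the tests and the alternatives were fixed before the data were examined, as was the rule for naming genes. Values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 8 arrays with group as the only term. A transcript was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all 15473 transcripts, with no filter on level. The rule named M1BP, the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between groups, and members of lists that passed. With 17 transcripts named, all 17 are given, a choice made after the values were seen, along with 2 unnamed transcripts for each direction. The ranges of level, and the level of 7 taken as the top of the dim range, were also set after the values were seen. Values are means ± SD over 4 arrays, differences are M1BP RNAi minus LacZ RNAi on the log2 scale, and SE is the moderated standard error.

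The groups share replicate numbers 1 to 4. The deviations of same-numbered arrays from their group means were correlated across transcripts, with r = 0.66, 0.66, 0.48 and 0.67 for numbers 1 to 4, and each of the 8 arrays correlated best with its own number in the other group. All 4 correlations exceeded 0.1, the bound set for treating numbers as pairs, so the fit with the replicate number as a block is called the paired fit and is given where it changes a call. The labels do not say what a number stands for. No 2 arrays held identical values, and correlations between arrays ran from 0.962 to 0.995.

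The procedure was tested on simulated data with the variance of the 15473 transcripts, a within-pair correlation of 0.6 and 200 changed transcripts. Without the block, 26.9% of 1.5-fold, 71.6% of 2-fold and 93.9% of 4-fold changes were called, with 1 false call. The paired fit called 41.8%, 88.1% and 98.5%, with 6 false calls. The simulated transcripts were independent of each other, shared 1 within-pair correlation and had the same change in every pair. These rates need not hold for the real arrays. Alternatives were the block, median centring, a second quantile normalization, array weights, filters on level, a trended robust prior, stricter thresholds, an ordinary pooled-variance test and leaving out each array. Fits within replicates 1 and 2 or 3 and 4, fits with that division as a term, paired fits without each pair, and the comparison of these sets on the within-pair differences were added after seeing the data.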

Results

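Expression was compared between S2R+ cells treated with double-stranded RNA against M1BP, a zinc-finger protein that binds the core promoter element Motif 1, and cells treated with control double-stranded RNA against LacZ. The question was which transcripts change when M1BP is depleted. Each group had 4 arrays with 15473 transcripts. The arrays had similar medians, from 7.91 to 8.01 on the log2 scale. A mean level under 7, in the dim mode of the distribution, was found for 6941 transcripts (44.9%).

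The named transcript of His4r, a replication-independent gene for histone H4, rose in M1BP RNAi cells. Its log2 value was 12.1 ± 0.57 (SD, n = 4) with LacZ RNAi and 13.7 ± 0.22 (SD, n = 4) with M1BP RNAi, a difference of 1.55 (SE 0.26) or 2.92-fold (limma, adjusted p = 0.0064). Dyrk3, which encodes a dual-specificity protein kinase, fell from 10.6 ± 0.30 to 9.51 ± 0.28 (SD, n = 4), a difference of -1.06 (SE 0.19) or 2.09-fold (limma, adjusted p = 0.0083). In both transcripts all 4 arrays of one group lay above all 4 of the other. Histone H4 is encoded by a multigene family with the same protein sequence, so signal from other H4 transcripts cannot be separated from His4r here. The His4r difference was 1.85 in replicates 1 and 2 and 1.25 in replicates 3 and 4. For Dyrk3 these differences were -0.85 and -1.27, and within replicates 1 and 2 alone Dyrk3 did not pass (limma, adjusted p = 0.141). His4r and Dyrk3 were the only transcripts past the threshold among the 17 tied to a single gene.

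In the paired fit, 6 more of the 17 passed, making 3 higher and 5 lower. LanA, a laminin alpha chain and the one haemocyte marker that was named, was 0.51 higher (SE 0.12 in the paired fit, limma adjusted p = 0.0168, against 0.0579 without the block). LanA passed in 4 of the 19 alternatives, among them the unblocked fit without LacZ RNAi replicate 1 (limma, adjusted p = 0.0371). Fatp1, a fatty acid transport protein, was 0.41 higher (paired adjusted p = 0.0348, limma, against 0.228). Fatp1 passed in 2 of the 19 alternatives, the paired fit and the unblocked fit without LacZ RNAi replicate 4 (limma, adjusted p = 0.0368). The lower transcripts included kis, a trithorax-group chromatin remodeller, at -0.49 (paired adjusted p = 0.0128, limma, against 0.073). CG16974 was at -0.55 (paired adjusted p = 0.0052, limma, against 0.465). Wdr24, a subunit of the GATOR2 complex that acts in amino acid signalling to TORC1, was at -0.45 (paired adjusted p = 0.0208, limma, against 0.0929). The nucleolar gene sle was at -0.36 (paired adjusted p = 0.0486, limma, against 0.388). Of the 19 alternatives, kis and CG16974 passed in 2 each, and Wdr24 and sle in 1 each, the paired fit. In each of these 6 the 4 pairs had the same sign, though the paired fit selected them on the same arrays.

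The other 9 named transcripts passed neither fit. A second GATOR2 subunit, mio, differed by -0.04 (SE 0.17, or 0.10 in the paired fit). The histone deacetylase gene HDAC3 differed by 0.21 (SE 0.14, paired 0.11), and SuUR, a regulator of replication in heterochromatin, by 0.13 (SE 0.25, paired 0.13). Values for the ubiquitin-activating enzyme gene Uba1 and the spectrin gene alpha-Spec were 0.12 (SE 0.28, paired 0.11) and -0.15 (SE 0.14, paired 0.11). For rdx, a Hedgehog pathway gene, the difference was 0.03 (SE 0.14, paired 0.14), and for fend -0.07 (SE 0.36, paired 0.15). The remaining 2 lay in the dim range on every array, where a difference cannot be told from background. CG31178 was at 4.99 ± 0.10 with LacZ RNAi and 4.96 ± 0.03 with M1BP RNAi (SD, n = 4), and the phosphate transporter gene NaPi-III at 5.61 ± 0.27 and 6.05 ± 0.59 (SD, n = 4). Among the 27 transcripts tied to several genes, 1 was higher and 2 were lower, or 3 and 5 in the paired fit.

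**Figure D1:**
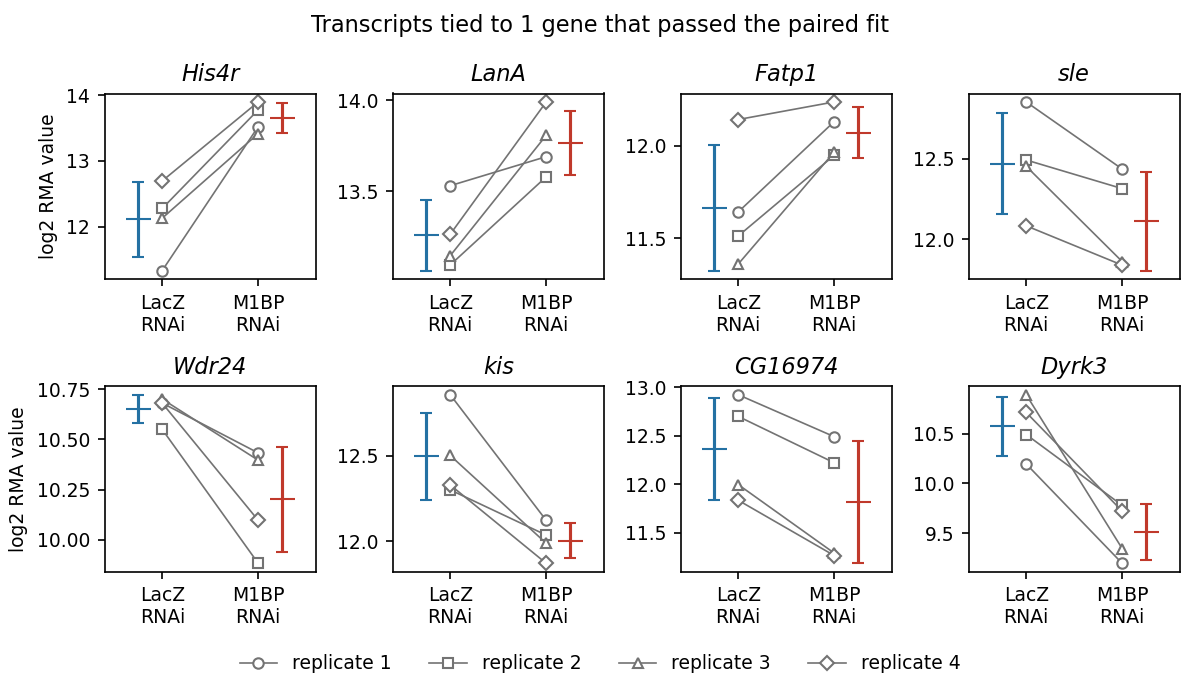
Log2 RMA values (vertical axes, a separate range in each panel) of the 8 transcripts tied to 1 gene that passed the paired fit, by treatment (horizontal axes). Grey lines join arrays with the same replicate number and coloured bars are the mean ± SD of 4 arrays; the 4 lines slope the same way in every panel, and the groups do not overlap for His4r, Dyrk3, LanA, kis and Wdr24.

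Over all 15473 transcripts, 656 were higher and 658 lower in M1BP RNAi cells (limma, adjusted p under 0.05), together 1314 or 8.49%. The direction was the same in all 4 pairs for 656 of the higher and 657 of the lower transcripts. They were selected on these same arrays, so this is no separate support. The paired fit called 3405 transcripts (22.0%), 1937 higher and 1468 lower, and included all 1314 calls with the same sign. The count without the block fell to 875 when M1BP RNAi replicate 3 was left out, with 374 higher transcripts. The higher transcripts numbered 422 without M1BP RNAi replicate 2, 410 without M1BP RNAi replicate 4 and 378 without LacZ RNAi replicate 3. In 2210 transcripts (14.3%) the groups did not overlap, where chance gives 2.86% if arrays are exchangeable. At an unadjusted p under 0.05 there were 3132 transcripts, where chance gives 774. Both chance values ignore the pairing by replicate number.

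Large falls were more frequent than large rises. The median fold was 2.48 among the lower and 1.86 among the higher. A change of at least 2-fold was found in 422 lower and 243 higher transcripts, or 471 and 367 in the paired fit. At least 1.5-fold there were 613 lower and 582 higher. The paired fit reversed that order, with 943 lower and 1129 higher. At least 4-fold the counts were 181 and 28, at least 8-fold 66 and 5, and at least 16-fold 12 and 0. In each of the 4 pairs taken alone, differences of at least 4-fold were more often falls, with 162 against 37, 153 against 34, 222 against 93 and 230 against 64. The 181 transcripts with 4-fold falls had a median level of 11.7 in LacZ RNAi cells and 8.72 in M1BP RNAi cells, and 36 of them reached a mean under 7. For the 28 with 4-fold rises the median level went from 7.89 to 10.6, and 6 of them started under 7. Leaving out M1BP RNAi replicate 1 raised the 4-fold rises to 43, with 211 falls of that size.

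Calls in both directions were found in every range of level but were rare in the dim range. Of the 6941 transcripts with a mean under 7, 37 (0.53%) were higher and 25 (0.36%) lower. A level under 7 cannot be told from background, so these dim calls are uncertain in both fits. In the ranges above it, 6.49% to 10.2% of transcripts were higher and 7.26% to 7.53% lower. Between 7 and 10 there were 176 higher and 188 lower among 2591 transcripts, between 10 and 13 286 and 332 among 4407, and at 13 or more 157 and 113 among 1534. The paired fit gave 176 higher and 115 lower under 7, 539 and 410 between 7 and 10, 900 and 709 between 10 and 13, and 322 and 234 at 13 or more, with the higher transcripts more numerous in each range. The 4-fold falls lay mainly between 7 and 10 (80 transcripts) and between 10 and 13 (81 transcripts).

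**Figure D2:**
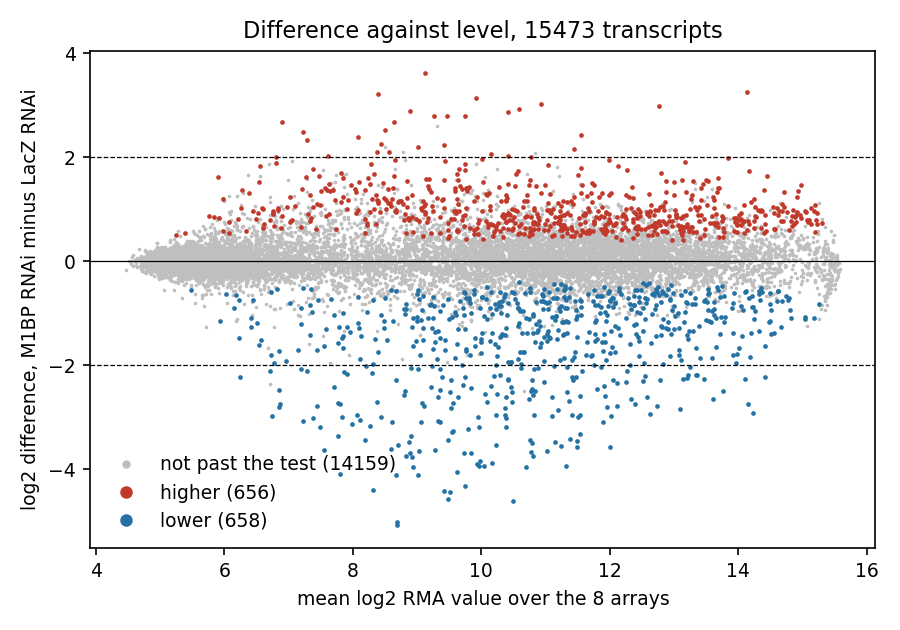
Log2 difference between M1BP RNAi and LacZ RNAi (vertical axis) against the mean log2 RMA value over the 8 arrays (horizontal axis), 1 point per transcript, with dashed lines at 4-fold. Red points are the 656 higher and blue points the 658 lower transcripts; 181 blue points and 28 red points lie beyond the dashed lines.

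The largest measured differences were in transcripts that the sources used here do not name. FBtr0084492 fell from 11.2 ± 0.50 to 6.15 ± 0.39 (SD, n = 4; limma, adjusted p = 1.5e-05). FBtr0073363 fell from 11.2 ± 0.37 to 6.18 ± 0.54 (SD, n = 4; limma, adjusted p = 1.6e-05). Both ended in the dim range, where a level cannot be told from background, so their folds are bounds. With 7 as the floor, FBtr0084492 was at least 18.8-fold lower and FBtr0073363 at least 18.3-fold lower. FBtr0087610 rose from 7.31 ± 0.56 to 10.9 ± 0.68 (SD, n = 4), 12.2-fold (limma, adjusted p = 0.00036). FBtr0071481 rose from 12.5 ± 1.83 to 15.8 ± 0.16 (SD, n = 4; limma, adjusted p = 0.0279). Its fold is not given, because the M1BP RNAi level lay near the highest values of the arrays, 15.86 to 15.98, and saturation was not measured. The call for FBtr0071481 was lost when LacZ RNAi replicate 2 or 3 or any 1 of the 4 M1BP RNAi arrays was left out, with adjusted p from 0.0511 to 0.0738 (limma). Without LacZ RNAi replicate 1 its measured log2 difference dropped from 3.26 to 2.38, with an adjusted p of 0.0016 (limma).

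Arrays also differed by replicate number. After the group means were removed, the first component held a share of 0.549 of the remaining variance and put both arrays of replicates 1 and 2 on one side and those of replicates 3 and 4 on the other. This division was read from the arrays themselves and the labels do not give it. Within replicates 1 and 2, M1BP RNAi gave 247 higher and 383 lower transcripts. Within replicates 3 and 4 it gave 766 higher and 677 lower. The sets shared 514 calls, all in the same direction. Independent lists would share 58.8 if every transcript were equally likely to be called. Calls were rare in the dim range, so this baseline may be too low. Across transcripts, which are not independent replicates, the differences of the sets had r = 0.816, and no arrays were shared between them. The M1BP RNAi effect itself was compared between the sets on the 4 within-pair differences, 2 against 2. This test, added after seeing the data, called 128 transcripts (limma, adjusted p under 0.05), 102 of them with the larger difference in replicates 3 and 4, and 26 were among the 1314. An interaction term fitted to the 8 arrays without the pairing called 0 (limma, adjusted p under 0.05) and 685 at an unadjusted p under 0.05, so the call depends on the pairing. The other divisions of the pairs called 0, with at most 668 transcripts at an unadjusted p under 0.05 against 1624 for this one, where chance gives 774. Those divisions leave any difference between the sets in the residual spread, so their counts are no baseline for chance. Of the 1314 changed transcripts, 851 (64.8%) had the larger difference in replicates 3 and 4.

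**Figure D3:**
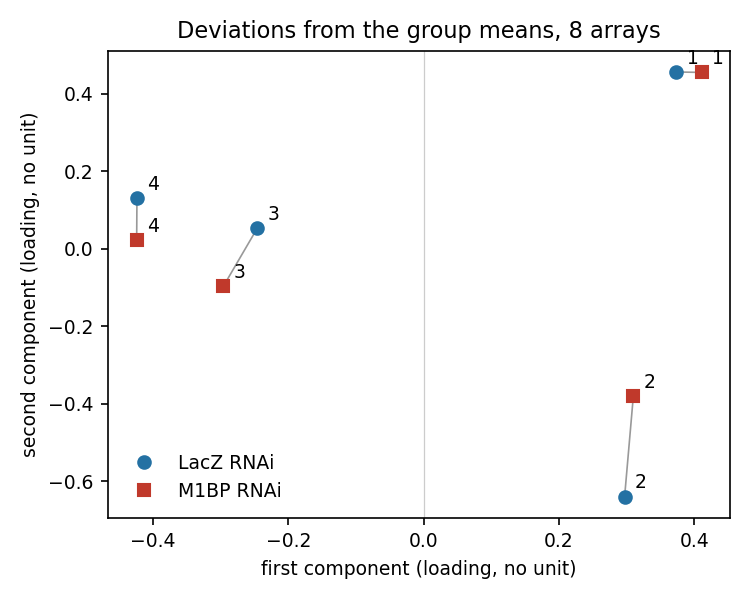
First and second component (loadings, no unit) of the 8 arrays' deviations from their group means, with replicate numbers beside the points and lines joining equal numbers. Replicates 1 and 2 lie at first-component loadings from 0.30 to 0.41 and replicates 3 and 4 from -0.42 to -0.25, in both groups.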

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

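For the 17 named transcripts, the 4 unnamed ones and the array medians, each group of 4 arrays was examined for an array far from the other 3. Of 44 groups, 3 had one, and chance alone gives about 1 in 20. The mio value of M1BP RNAi replicate 1 was 8.89, with the other 3 arrays between 8.45 and 8.50. For NaPi-III, M1BP RNAi replicate 3 read 6.93, with the others between 5.70 and 5.88. For Wdr24, LacZ RNAi replicate 2 read 10.55, with the others between 10.68 and 10.70.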

How the results depend on the processing

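The within-set fits and the replicate set as a term were chosen after seeing the data. Of the counts of changed transcripts, the replicate block gave 3405 (1937 higher, 1468 lower), and the replicate set as a term 2487 (1398 higher, 1089 lower). At an adjusted p under 0.01 there were 646 (242 higher, 404 lower), at a fold of at least 2 665 (243 higher, 422 lower), and with the pooled-variance test 792, of which 347 were higher. Within replicates 1 and 2 there were 630 (247 higher, 383 lower), and within replicates 3 and 4 the rises of at least 4-fold came to 67. Leaving out 1 array gave 875 to 1278 changed and 374 to 611 higher transcripts and 22 to 43 rises of at least 4-fold. The lowest count, 875, came without M1BP RNAi replicate 3, and 374 of these were higher. Of the 1314 transcripts, 855 to 1084 kept their call when 1 array was left out. The paired fit without 1 pair called 2436 to 2820. The counts followed were those of changed, higher and lower transcripts and of falls and rises of at least 4-fold. Every other value of these counts stayed within 1.5 times its main value. This covers median centring, a second quantile normalization, array weights, the filters on level and the trended robust prior. No call changed sign. His4r passed in all 19 alternatives (adjusted p from 0.00026 to 0.0474) and Dyrk3 in 18. The named transcripts that gained a call did so 12 times, 6 of them with the replicate block, and apart from those 6 the block changed no call of a named transcript. FBtr0071481 lost its call in 8 alternatives (adjusted p up to 0.122). The causes of these moves were not tested beyond the number of arrays or the stricter threshold that a setting imposes. The planned analyses of the M1BP transcript, the gene lists and the promoter motifs were not run, and so neither were their alternatives. Without detection calls, a level under 7 cannot be told from background.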

Other observations

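The test of a shared shift was chosen after its result was seen. The other tests were set before their own results, though after the patterns they address had been noticed.

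Fewer changed transcripts came from any other split of the 8 arrays. Only 1 of the 35 splits, the real one, gave as many as 1314, and the highest other count was 878. This excludes chance only if the 8 arrays are exchangeable, which the pairing by replicate number contradicts. The count of 878 came from replicates 1 and 2 against 3 and 4, which points to a structure of the arrays by replicate number. With the group in the model, 2405 transcripts differed between these sets (limma, adjusted p under 0.05). This fit took the 8 arrays as independent, though same-numbered arrays deviated together, and the division was read from these same arrays. The 2405 is therefore likely too high and is no separate support for the division. The other 33 splits gave 0. They leave the M1BP RNAi difference in the residual spread, so this 0 is no baseline for chance. In the paired fit, 1 of the 8 splits that part all 4 pairs, the real one, gave 3405, with 0 as the highest other, but 8 splits, the ones that respect the pairs, are too few for a share under 0.05. The 0 of these other splits has the same limit.

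Large falls outnumbered large rises. A ceiling of the scale was tested on 4836 transcripts with a mean from 8 to 12, where rises have room: the lowest ratio of 4-fold falls to rises in the 4 pairs was 2.63, above the bound of 2 set for rejecting it. Counting runs of consecutive transcript numbers once left 163 falls against 28 rises, a ratio of 5.82, so runs of neighbouring identifiers do not account for the excess. Transcripts of 1 gene without consecutive numbers could not be grouped, since most identifiers were not tied to a gene. Repeated counting of a few genes therefore stays open. A shift shared by all transcripts and removed by the normalization between arrays cannot be told apart: some constant must make the counts equal (0.61 on the log2 scale here), so this value decides nothing, and normalized arrays hold none that does. A direct loss of transcription after M1BP depletion may also account for the falls, but this was not tested, since no binding data or promoter sequences were used.

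Replicates 1 and 2 stood apart from 3 and 4 in both groups. The first component's share of 0.549 was 0.551 after each array's trend on the mean level was removed. A level-dependent trend left in these values therefore does not account for it. The normalization had already brought the arrays to a shared distribution, so an earlier trend could not be tested. The share was 0.614 among the 7739 transcripts with a mean of at least 8, which argues against the background of dim transcripts as its cause. A difference in culture, RNA preparation or hybridization between the sets may be behind it and was not tested, because the labels give no date. Across transcripts the set difference (3 and 4 minus 1 and 2) had r = 0.253 with the M1BP RNAi difference, and transcripts are not independent replicates.

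Log2 differences were weakly correlated between transcripts with neighbouring identifiers, most of which were not tied to a gene. Over 12668 pairs of consecutive numbers, the log2 differences had r = 0.14, against at most 0.0275 in 200 shuffles of the identifiers. In 221 such pairs both transcripts were called, 171 of them in the same direction. Counted as runs, the 656 higher transcripts made 576 and the 658 lower ones 567.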
